A study of Mus musculus with 32 samples.

How the data were processed

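T cells were sorted from tumour, blood, spleen and tumour-draining lymph node of 4 mice carrying MC38 tumours, a transplantable mouse colon carcinoma line, and their RNA and T cell receptor (TCR) chains were sequenced from single cells on the 10x Chromium platform. The 32 samples were 16 RNA libraries (4 tissues from each of 4 mice) and 16 TCR samples, of which 7 came with a contig file in the sources used here (tumour of mice 1, 2 and 4, draining lymph node of mice 1 and 4, blood of mouse 4, spleen of mouse 3); the other TCR samples were not analysed here. Per the labels, cells were stained for viability, CD45, TCR beta and CD90.2, T cells were enriched by negative selection, and the tumour cocktail held an antibody against CD34 that removes MC38 cells. Markers used for the sort were not read as findings. The submitters' processing notes name Cell Ranger 2.1.0, Seurat 2.3.0 and the mm10 build (GRCm38), without a role or an order for each, and the counting settings were not given in the sources used here.

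The deposited table held whole UMI counts, which the authors had neither normalised nor transformed, for 64449 cells and 16136 genes. The authors' matrix files, per library, held the counts of more barcodes: of the table's cells 62321 were found in them, and over 16098 genes no entry (0) differed. For mice 1 and 2 the matrices held 85.98% to 99.5% of the table's cells, and for mice 3 and 4 they listed 737280 barcodes. The labels do not say how the table's cells were chosen. Tested on the files, each cell had at most 5% mitochondrial UMIs and 442 to 5997 genes, and each of the 28027 table cells of the 7 TCR libraries had exactly 1 productive TRA and 1 productive TRB contig. The deposited contig annotations of the authors (chain, V and J genes, CDR3 sequences, UMI counts per contig) were used as given. Gene symbols were joined to Ensembl IDs through the matrix files (16098 genes), and 16042 of them to positions in GENCODE M21 (mm10), where each position covers the whole gene, exons, introns and untranslated regions together. UMIs remove PCR copies, but reads of near-identical paralogs (Gzmc, Gzmd, Gzme and Gzmf, the Klra genes, Ly6c1 and Ly6c2, Tgtp1 and Tgtp2, and ribosomal protein genes with their pseudogenes) can be split or dropped in counting, so values of single members are less certain.

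Total UMIs per library ran from 4010433 (blood of mouse 4) to 63616302 (tumour of mouse 1), cells per library from 945 to 6773, and median UMIs per cell from 3932 to 9550. Cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.2 with igraph 0.11.9), which gave 22 clusters. A cluster took a cell type name only where at least 3 of the type's markers, fixed beforehand, were seen in at least 20% of its cells and at least 1.2-fold above the rest. Scrublet, with 6% expected, called 77 doublets (0.119% of the cells). The cause of this low rate was not tested. The called cells were left out, and an alternative left out the tenth of cells with the highest scores. Cells of 2 clusters led by myeloid or B cell genes (526 cells) were left out, and 63847 cells were kept.

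Cell classes were gates on UMIs. A T cell had UMIs of at least 2 of 6 genes (Cd3d, Cd3e, Cd3g, Trac, Trbc1, Trbc2). CD8 cells (34106) had at least 1 UMI of Cd8a or Cd8b1 and none of Cd4. Regulatory T cells (Treg, 2318) had at least 1 UMI each of Foxp3 and Cd4 and none of Cd8a or Cd8b1. CD4 conventional cells (13515) had at least 1 UMI of Cd4 and none of the other genes. The other 13908 cells (21.8%) fell in no gate. Gate genes were not read as findings. Treg libraries held 24 to 478 cells. Because a deeper cell passes a gate more readily, shares of cells were computed after each cell was thinned to 2000 UMIs, with 1000 UMIs and no thinning as alternatives. Cells under 2000 UMIs were left out (tumour 165, blood 136, spleen 310, draining lymph node 95). Cycling cells had UMIs of at least 2 of 10 cell cycle genes. Tissues were compared by two-sided exact permutation tests over the 70 arrangements of 4 and 4 libraries, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment over the 12 tests.

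For each class the counts were summed per library and tested in 1 fit over the 16 libraries with edgeR 4.0.16 (TMM scaling, filterByExpr with minimum count 10, quasi-likelihood F test, two-sided, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). CPM are edgeR's TMM-scaled UMI counts relative to the library total, given as mean ± SD over 4 mice, and fold changes are log2 with their SE. Where a group had no UMI, the fold was bounded by 3 UMIs over the group's 4 libraries, and with 1 to 3 UMIs a ratio of pooled counts is given with its exact 95% interval. Intervals and floors cover counting error only. Gene lists were tested with camera of limma 3.58.1 (correlation 0.01) and again with an estimated correlation, adjusted over the lists of a comparison. Of 27 lists fixed beforehand, 19 described cell states (naive and central memory, inhibitory receptors and exhaustion, cytotoxic granules and effector cytokines, tissue residency, circulating effector, interferon response, cell cycle, effector Treg, Th1, Tfh, Th17, Th2, glycolysis, hypoxia targets, immediate early and heat shock, chemokine receptors, costimulatory receptors, ribosomal proteins, mitochondrially encoded genes) and 8 other cells (myeloid, B cell, erythroid, platelet, MC38 carcinoma and stroma, NK cell, gamma-delta T cell, NKT and MAIT). A list needed at least 3 tested members. The B cell, erythroid, platelet, carcinoma and stroma, and gamma-delta T cell lists had fewer in each comparison, as had the myeloid, NK cell, NKT and MAIT, and Th17 lists in Treg, and these were not tested. Some genes stand in more than 1 list. In each list called, the median and the mean of the log2 fold changes had the sign of the test.

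Genes were named by a rule. It took the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 50 CPM in 1 of the tissues and the same direction in 4 mice, up to 4 members with the smallest p of each list called, and a set named whatever the result (Pdcd1, Havcr2, Lag3, Ctla4, Tigit, Tox, Gzmb, Ifng, Ccr7, Tcf7, Klrg1, Cxcr6 and Mki67 in CD8, Ccr8, Tnfrsf9, Il10 and Klrg1 in Treg, Ifng, Bhlhe40 and Cd40lg in CD4 conventional cells). Some genes that the rule takes are not reported here. Gate genes, receptor and immunoglobulin segments, Xist and Y-linked genes were not named as largest changes. Each named gene that passed a tissue comparison moved the same way in 4 of 4 mice. The rule, gates, lists, tests and alternatives were fixed before the data were examined, but for those given below as chosen later.

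A clone was the set of cells of a mouse with the same CDR3 nucleotide sequences of the TRA and TRB chains. Shares of cells in clones of at least 2 cells were computed at 910 cells per library, and at 188 cells per gate, as means of 200 random draws (seed 7), with exact (Clopper-Pearson) 95% intervals for the shares of all cells. Tumour CD8 cells of clones of at least 3 cells and of clones of 1 cell were summed in mice 1, 2 and 4 and tested with edgeR with the mouse as a block.

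The numbers of the mice pair the libraries. After the tissue means were removed, CD8 profiles of the same mouse correlated across tissues with a mean r of 0.320, against 0.237 for the other mouse of the same pair (mice 1 and 2, or 3 and 4) and -0.276 between pairs. The values were 0.271, 0.233 and -0.252 in CD4 conventional cells, and 0.148, 0.154 and -0.152 in Treg. Genes are not independent replicates in these correlations. The 2 mouse pairs thus stood apart in each tissue, and the cause was not tested. Alternatives were a mouse block, DESeq2 1.42.0, edgeR with other size factors, no filter on low counts, other doublet handling, classes from clusters, only the tissues compared, either mouse pair alone, and each mouse left out.

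Tests were checked on data simulated from these libraries with 200 genes changed, far fewer than in the tumour comparisons, where rates may differ. At 1.5-fold, 2-fold and 4-fold, 47.8%, 71.6% and 97.0% of changed genes were recovered for CD8 tumour against spleen (3 false calls), 35.8%, 67.2% and 95.5% for CD8 blood against spleen (7), 7.46%, 64.2% and 97.0% for Treg tumour against blood (6), 34.3%, 74.6% and 92.4% for Treg tumour against spleen (5), 34.3%, 68.7% and 92.4% for CD4 conventional tumour against spleen (6), and 52.2%, 73.1% and 89.4% for the clone comparison (12). Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.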

Results

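UMIs were counted in 64449 single T cells from tumour, blood, spleen and draining lymph node of 4 mice, with 1 library per tissue and mouse (n = 4 per tissue). Tumour libraries of mice 1 to 4 held 6147, 5108, 3454 and 5115 cells with medians of 8900, 9550, 7105 and 7982 UMIs per cell. Blood libraries held 4035, 4740, 1927 and 945 cells with medians of 5422, 5330, 4176 and 3932 UMIs. Spleen libraries held 6773, 5430, 3487 and 2265 cells with medians of 4975, 6137, 5570 and 6170 UMIs, and lymph node libraries 5786, 5928, 1870 and 1439 cells with medians of 6045, 6555, 6398 and 6436 UMIs. The series title names STARTRAC, a set of indices for following T cell clones across tissues and states. The questions were how tumour T cells differed from those of blood and lymphoid organs, and the size and sharing of clones. Libraries of mice 1 and 2 stood apart from those of mice 3 and 4. Of 22 clusters, 15 took over 95% of their cells from 1 of these pairs. CD8 cells with exhaustion markers formed a cluster of 7790 cells, 99.6% from mice 1 and 2, and a cluster of 4569 cells from mice 3 and 4 alone. Tissues were therefore compared through gates applied alike to each library, with each pair's own gene count beside the pooled one.

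CD8 cells made up a larger share of T cells in tumour than in the other tissues, Treg a larger share of Cd4-positive cells. More of the tumour's CD8 cells carried transcripts of dividing cells. The CD8 share was 88.7% ± 5.75 in tumour (SD, n = 4, at 2000 UMIs per cell), 61.8% ± 3.57 in blood, 68.6% ± 4.37 in spleen and 73.3% ± 3.53 in lymph node (83.6%, 50.8%, 58.6% and 63.3% without thinning). Cd4 was missed more often than Cd8b1, so the gates overstate the level of the CD8 share. A Cd4 UMI was seen in 41.4% to 67.2% of cells of the naive CD4 clusters. For Cd8b1 in the naive CD8 clusters it was 91.2% to 99.5%. By cluster, blood of mouse 1 held 1360 CD8 and 2094 CD4 conventional cells (1451 and 1371 by gate without thinning). The tumour of this mouse held 5144 and 195 by cluster. Treg made up 37.3% ± 6.05 of Cd4-positive cells in tumour, 3.87% ± 1.32 in blood, 2.90% ± 1.18 in spleen and 4.0004% ± 1.13 in lymph node (56.2%, 8.97%, 5.50% and 6.63% without thinning). Cycling cells were 11.3% ± 3.45 of CD8 cells in tumour, 0.684% ± 0.406 in blood, 0.941% ± 0.654 in spleen and 0.802% ± 0.602 in lymph node (22.1%, 1.43%, 1.30% and 1.97% without thinning). Each of these 9 differences had exact permutation p = 0.0286, the smallest that 70 arrangements allow (adjusted p = 0.0343), and was higher in tumour in 4 of 4 mice. In mice 1 and 2, and in mice 3 and 4, tumour exceeded blood by 28.7 and 25.0 percentage points in the CD8 share, by 30.4 and 36.6 in the Treg share and by 13.0 and 8.25 in cycling CD8 cells.

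Among Treg, cycling cells were 5.67% ± 1.40 in tumour (SD, n = 4), 4.06% ± 4.93 in spleen and 7.77% ± 5.59 in lymph node, and 0 of 76 cells in blood. This allows up to 3.95% of blood Treg with such UMIs at 2000 UMIs per cell and does not limit the share of dividing cells. Without thinning the shares were 18.003%, 8.30%, 13.5% and 10.6% in that order. Tumour exceeded blood at 2000 UMIs (exact permutation p = 0.0286, adjusted p = 0.0343), but did not pass at 1000 UMIs. Against spleen and lymph node no difference was detectable at this depth (exact permutation p = 0.514 and 0.543, adjusted p = 0.543 for both). Tumour minus lymph node was 3.53 percentage points in mice 1 and 2 and -7.74 in mice 3 and 4. Lymph node had 1 of 39, 1 of 27, 2 of 19 and 1 of 7 cycling Treg, too few to compare pairs. As a background for the Foxp3 gate, a Foxp3 UMI was seen in 1.42% ± 0.686 of tumour CD8 cells, 0.765% in blood, 0.610% in spleen and 0.563% in lymph node. The mean library medians were 9097, 5389, 6416 and 6895 UMIs in these cells and 5772, 4274, 5190 and 5760 UMIs in Cd4-positive cells.

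**Figure D1:**
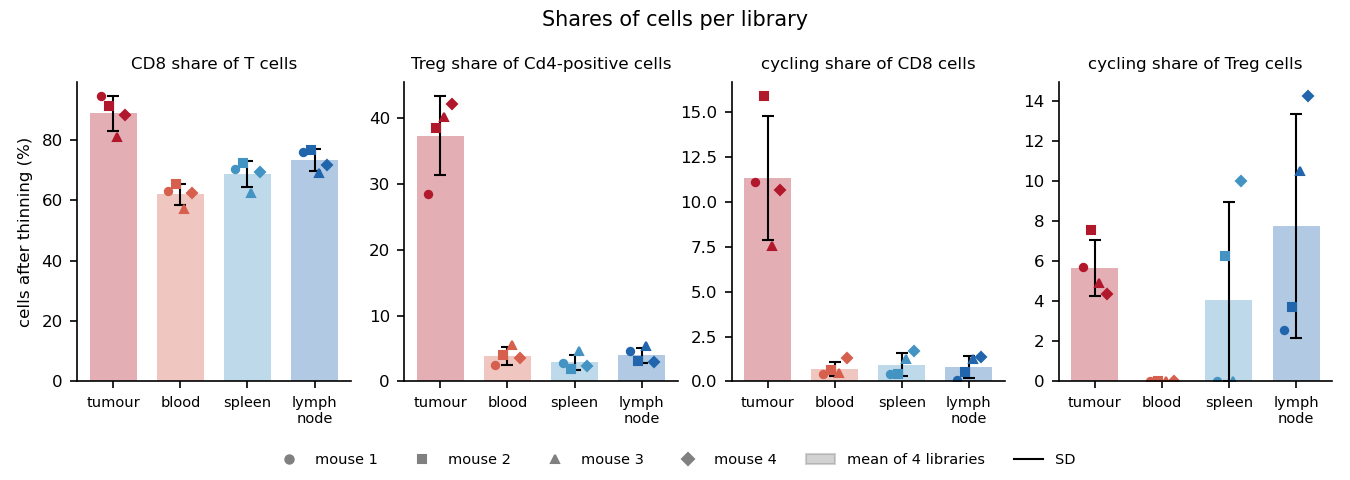
Percent of cells (linear axis from 0) in each gate by tissue, for cells thinned to 2000 UMIs; points are the 4 mice, bars the mean and whiskers 1 SD, clipped at 0. The CD8 share of T cells was 88.7% in tumour and 61.8% in blood.

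Tumour CD8 cells differed from those of the spleen in granzymes, inhibitory receptors and naive genes, among others. Gzmf, a granzyme of long-stimulated cytotoxic cells, averaged 538 ± 432 CPM in tumour and 0.0878 ± 0.102 in spleen (SD, n = 4, log2 fold change 12.07, SE 1.05, adjusted p = 3.61e-07). Pdcd1, which encodes the programmed death receptor, averaged 964 ± 134 and 3.02 ± 1.22 CPM (log2 fold change 8.38, SE 0.53, adjusted p = 1.39e-09). Tcf7, a transcription factor of naive and memory cells, fell from 343 ± 16.8 to 11.2 ± 7.73 CPM (log2 fold change -4.96, SE 0.33, adjusted p = 3.07e-09). Of 11396 genes tested, 3786 were higher and 3639 lower in tumour (edgeR). The total was 8230 in mice 1 and 2 alone and 6049 in mice 3 and 4 alone. The positions on mm10 are chromosome 1, 94038305 to 94052553 for Pdcd1 (ENSMUSG00000026285), chromosome 14, 56205263 to 56211417 for Gzmf (ENSMUSG00000015441) and chromosome 11, 52252371 to 52283014 for Tcf7 (ENSMUSG00000000782).

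The largest rises against spleen, beside Gzmf, were those of its neighbours Gzmd (160.1 ± 116 CPM, ratio of pooled counts 4846, 95% interval 1341 to 40014), Gzme (150.3 ± 99.5 CPM, ratio 2992, interval 1024 to 14507) and Gzmc (153 ± 155 against 0.102 CPM, log2 fold change 10.05). Spp1, the secreted matrix protein osteopontin, rose as well (194 ± 154 against 0.167 ± 0.0960 CPM, log2 fold change 10.37, SE 0.94), as did Gm156, a lectin-like gene of the natural killer receptor region (85.1 ± 54.3 CPM, at least 1831-fold higher, since no UMI was seen in spleen). The largest falls were those of Ccr9, a gut homing receptor (0.0896 against 61.7 ± 4.91 CPM, log2 fold change -10.11), Dtx1, a Notch target (1.24 against 137 ± 14.2 CPM). Igfbp4, a gene of naive T cells, was next (2.89 ± 3.27 against 277 ± 44.3 CPM, log2 fold change -6.74), with Tmem108, Fam101b and Il6ra, an interleukin receptor (1.77 against 101 CPM).

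The inhibitory receptor and exhaustion list rose in all 14 tested members against spleen, and also 14 adjusted over the list alone (camera adjusted p = 3.32e-09, adjusted p = 0.0503 with an estimated correlation). Beside Pdcd1 it held the receptors Havcr2 (136 ± 29.0 against 1.06 ± 0.570 CPM, log2 fold change 7.003, SE 0.40), Lag3 (775 ± 140.2 against 4.04 ± 0.873 CPM, 7.58, SE 0.44), Ctla4 (575 ± 120.0 against 22.3 ± 1.89 CPM, 4.68, SE 0.31) and Tigit (489 ± 60.3 against 7.07 ± 1.28 CPM, 6.09, SE 0.41). It also held the transcription factors Nr4a2 (817 ± 147 against 14.3 ± 1.84 CPM, 5.84) and Tox (111 ± 20.8 against 47.1 ± 12.8 CPM, 1.24, SE 0.20, adjusted p = 3.91e-05), Entpd1 and Cd160. Of 17 cytotoxic granule and effector cytokine genes 16 rose (16 adjusted over the list alone, camera adjusted p = 5.99e-09, 0.0495 with an estimated correlation). They included Gzmb, the main killing protease (1625 ± 461 against 12.5 ± 3.92 CPM, log2 fold change 7.03, SE 0.69, adjusted p = 2.37e-07), Ifng, the cytokine interferon gamma (312 ± 39.1 against 6.84 ± 2.17 CPM, 5.46, SE 0.28). Other members were Fasl, a death ligand (253 ± 28.7 against 6.12 ± 1.14 CPM), Serpinb9, an inhibitor of granzyme B (618 ± 189 against 12.6 ± 1.49 CPM), and Nkg7 (3304 ± 278 against 669 ± 25.7 CPM, 2.304). Gzmb lies on chromosome 14, 56258838 to 56262260.

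Metabolism and interferon genes rose as well. Each of 13 glycolysis genes rose against spleen (13 adjusted over the list alone, camera adjusted p = 1.01e-08, adjusted p = 0.0664 with an estimated correlation). Among them were Tpi1 (472 ± 103 against 44.6 CPM), Aldoa (1343 ± 263 against 345 ± 15.6 CPM) and the lactate exporter Slc16a3 (59.8 ± 14.4 against 0.793 CPM). Of 11 hypoxia targets 10 rose, with Hilpda, a lipid droplet gene (374 ± 36.2 against 17.3 ± 2.75 CPM, log2 fold change 4.42), and Bnip3, a mitophagy gene (63.4 ± 27.0 against 5.58 CPM). Pdk1, a kinase that holds pyruvate from the mitochondria, fell (21.3 ± 1.73 against 84.0 ± 11.7 CPM, log2 fold change -1.98). The hypoxia list had camera adjusted p = 0.000979 and adjusted p = 0.107 with an estimated correlation. Of 20 interferon response genes 17 rose (camera adjusted p = 9.19e-06, adjusted p = 0.318 with an estimated correlation). Ly6a, a surface antigen of activated cells, was 1463 ± 69.3 against 66.8 ± 14.5 CPM (log2 fold change 4.46). Of 17 cell cycle genes 16 rose (camera adjusted p = 0.00116, adjusted p = 0.463 with an estimated correlation). Mki67, a proliferation marker, was 97.5 ± 22.2 against 18.2 ± 16.1 CPM (log2 fold change 2.49, SE 0.70, adjusted p = 0.00512).

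Of 12 Th1 genes 11 rose against spleen (camera adjusted p = 3.11e-07, 0.048 with an estimated correlation). They included Tbx21, the Th1 master regulator (200.4 ± 13.8 against 17.3 ± 3.19 CPM, log2 fold change 3.55). Of 10 tissue residency genes 8 rose and 1 fell (camera adjusted p = 0.00399, adjusted p = 0.0503 with an estimated correlation). The chemokine receptor Cxcr6 was 712 ± 162 against 67.6 ± 11.1 CPM (3.3998, SE 0.17), Rgs1, a damper of chemokine signals, 712 ± 97.2 against 47.6 CPM and the integrin Itga1 34.3 against 0.531 CPM. Of 19 effector Treg genes 18 rose in these CD8 cells (camera adjusted p = 7.15e-09, adjusted p = 0.107 with an estimated correlation). The members named were activation genes that CD8 cells share with Treg: the receptors Tnfrsf9 (742 ± 139 against 15.3 ± 3.97 CPM, 5.61), Tnfrsf18 and Icos, and the actin regulator Capg (471 ± 68.3 against 26.9 CPM). Of 9 costimulatory receptors 7 rose and 1 fell (camera adjusted p = 0.000513, adjusted p = 0.176 with an estimated correlation).

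Each of 12 naive and central memory genes fell (12 adjusted over the list alone, camera adjusted p = 5.84e-09, adjusted p = 0.0503 with an estimated correlation). Beside Tcf7 these included Ccr7, which guides cells into lymph nodes (98.5 ± 34.4 against 439.5 ± 53.7 CPM, log2 fold change -2.16, SE 0.21). They also included Lef1 (15.1 ± 3.80 against 473 ± 97.3 CPM, -4.98) and Klf2, a regulator of exit from tissues (46.2 ± 16.5 against 944 ± 105 CPM, -4.36). All 16 ribosomal protein genes of the list fell (camera adjusted p = 1.23e-07, adjusted p = 0.2 with an estimated correlation), with Rplp1 at 2979 ± 239 against 8508 ± 1121 CPM. All 9 mitochondrially encoded genes of the list fell (camera adjusted p = 3.63e-05, adjusted p = 0.107 with an estimated correlation), with mt-Nd2 at 483 ± 82.4 against 1418 ± 126 CPM. Klrg1, a receptor of terminal effector cells, was 8.60 ± 3.58 against 3.21 ± 1.23 CPM and did not pass (adjusted p = 0.109). Markers of myeloid cells moved with the tumour: 8 of 9 rose in the CD8 gate (camera adjusted p = 0.00183, adjusted p = 0.137 with an estimated correlation). Fcer1g, an Fc receptor chain, was 71.7 ± 15.1 against 2.65 ± 0.866 CPM, C1qa, a complement gene, 2.50 ± 0.509 against 0.162 CPM and Cst3, a protease inhibitor, 174 ± 30.1 against 74.3 ± 4.26 CPM. Lists not called were chemokine receptors (5 up, 3 down of 11, adjusted p = 0.574), circulating effector (4 up, 2 down of 9, 0.363), immediate early and heat shock (11 up, 4 down of 18, 0.0862). The same held for Tfh (2 up, 4 down of 9, 0.373), Th17 (1 up of 4, 0.389), Th2 (2 up of 3, 0.36), NK cell (2 up, 1 down of 5, 0.36) and NKT and MAIT (2 up of 4, 0.139).

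**Figure D2:**
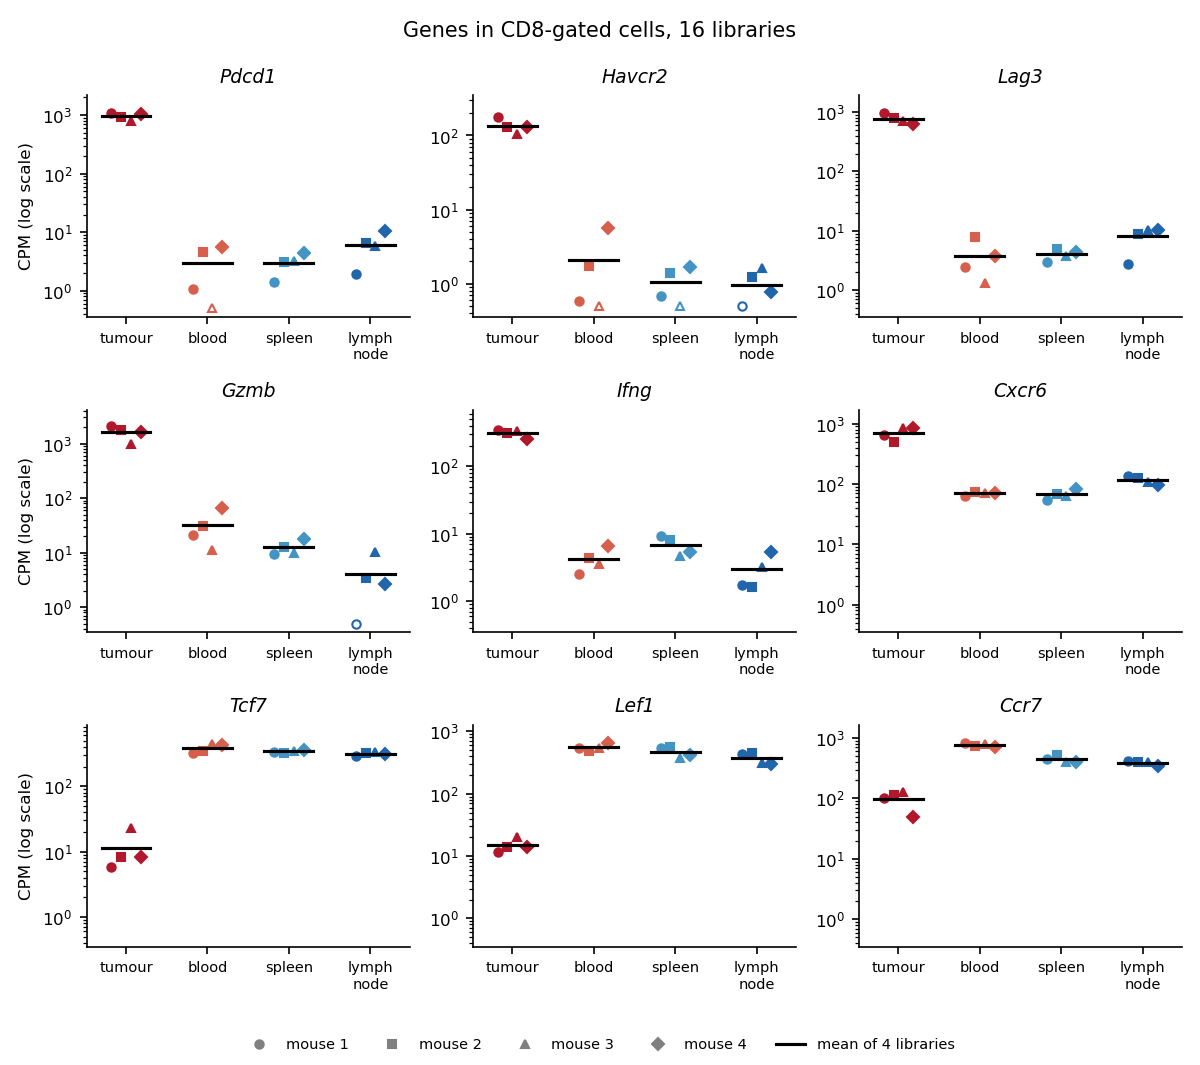
CPM after TMM scaling (log axis) of named genes in CD8 cells by tissue; points are the 4 mice, lines the means, and open symbols at the bottom are libraries under 0.5 CPM, the lowest level drawn. Pdcd1 averaged 964 CPM in tumour and 3.02 CPM in spleen, and Tcf7 11.2 and 343 CPM.

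Against blood, CD8 cells of the tumour showed the same groups and a rise of immediate early genes by camera, but no list's call held with an estimated correlation. Pdcd1 was 2.92 ± 2.56 CPM in blood (n = 4, log2 fold change 8.44, SE 0.56, adjusted p = 3.44e-09), Gzmb 32.4 ± 23.98 (5.76, SE 0.66), Havcr2 2.09, Lag3 3.83, Tigit 9.06, Ctla4 26.6, Tox 40.3, Ifng 4.23 and Cxcr6 70.3 CPM, each higher in tumour. Tcf7 was 386 ± 56.6 (-5.12, SE 0.34) and Ccr7 764 ± 60.4 CPM (-2.96, SE 0.21), each lower in tumour. No UMI of Gzmf, Spp1, Gzmd, Gzme or Gm156 was seen in blood CD8 cells. These were at least 5545-fold, 2056-fold, 1558-fold, 1442-fold and 883-fold higher in tumour. Rgs16, a signalling regulator, rose from 0.841 ± 0.375 to 672 ± 116 CPM. Ccr9, Igfbp4, Tmem108, Fam101b, Dtx1 and Gm43698 were the largest falls, Igfbp4 from 354 ± 51.1 CPM (log2 fold change -7.09). Of 11396 genes 3738 were higher and 3423 lower (edgeR). The total was 7822 in mice 1 and 2 alone and 5255 in mice 3 and 4 alone. With library size scaling alone the numbers were 4929 higher and 2349 lower. The median of all genes then moved by 0.25 on the log2 scale.

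Of 18 immediate early and heat shock genes 13 rose and 2 fell against blood (camera adjusted p = 0.000175, adjusted p = 0.288 with an estimated correlation). They included the early response factors Nr4a1 (398 ± 72.3 against 3.04 ± 0.863 CPM, log2 fold change 7.05), Egr1 (161 ± 26.9 against 4.62 ± 2.61 CPM) and Fos (131 ± 4.50 against 26.4 ± 1.12 CPM, 2.32, SE 0.16). The exhaustion list rose in 14 of 14 members (adjusted p = 0.065 with an estimated correlation, as in the brackets that follow), cytotoxic genes in 15 of 17 with 1 down (0.0639), effector Treg genes in 17 of 19 (0.197), glycolysis in 13 of 13 (0.0728), hypoxia targets in 9 of 11 with 1 down (0.22). Interferon response rose in 17 of 20, or 18 adjusted over the list alone (0.32), cell cycle in 16 of 17 (0.4), costimulatory receptors in 7 with 1 down (0.22), Th1 in 10 of 12 (0.0639) and tissue residency in 8 with 2 down of 10 (0.065). Naive genes fell in 12 of 12 (0.0639), ribosomal proteins in 16 of 16 (0.215) and mitochondrially encoded genes in 8 of 9 (0.11). The residency integrin Itgae was among the members that fell (5.44 ± 3.15 against 51.5 ± 14.6 CPM, log2 fold change -3.36). Myeloid genes rose in 6 of 9 with 1 down (camera adjusted p = 0.0412, 0.0585 with the mouse as a block, adjusted p = 0.32 with an estimated correlation), with Fcer1g at 13.1 CPM in blood. Klrg1 was 17.4 ± 11.8 CPM in blood and did not pass (log2 fold change -0.87, SE 0.73, adjusted p = 0.312), and with classes from clusters it was higher in tumour (2.999, adjusted p = 0.000155).

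Against lymph node, 3782 genes were higher and 3702 lower in tumour CD8 cells (edgeR, 8362 in all in mice 1 and 2 alone, 5929 in mice 3 and 4 alone). Genes of circulating effector cells joined the groups above. Of the 9 circulating effector genes 6 rose and 1 fell (camera adjusted p = 0.0218, adjusted p = 0.148 with an estimated correlation). Cx3cr1, a receptor of patrolling effector cells, was 56.0 ± 13.1 against 0.461 ± 0.349 CPM (n = 4, log2 fold change 6.998, SE 0.43, adjusted p = 1.16e-09). The transcription factors were higher too, Zeb2 at 33.7 ± 3.02 against 0.783 and Tbx21 200.4 against 6.05 ± 0.816 CPM. Klf3, a factor of quiescent cells, fell (6.82 ± 3.68 against 135 ± 20.8 CPM, -4.34). Klrg1 rose from 2.29 ± 2.71 CPM (2.48, SE 0.85, adjusted p = 0.0175). Areg, a growth factor, was 81.7 ± 63.2 against 0.228 CPM, and Gzme at least 3215-fold higher. Pdcd1 was 6.10 ± 3.44 (7.41) and Gzmb 4.14 ± 4.21 CPM in lymph node (8.77). Of the lists, cytotoxic (16 of 17) and Th1 (12 of 12) rose and held with an estimated correlation (adjusted p = 0.0339 and 0.0322). Exhaustion (14 of 14, adjusted p = 0.0649 with an estimated correlation, as in the brackets that follow), effector Treg (18 of 19, 0.114), glycolysis (13 of 13, 0.074), hypoxia (10 up, 1 down of 11, 0.113), interferon (16 up, 1 down of 20, 0.364), cell cycle (16 of 17, 0.396), costimulatory (7 up, 2 down of 9, 0.191), immediate early (11 up, 3 down of 18, 0.366) and tissue residency genes (8 up, 2 down of 10, 0.0649) also rose by camera, and these calls were lost with an estimated correlation. Naive (12 of 12, 0.0649), ribosomal (16 of 16, 0.215) and mitochondrially encoded genes (8 of 9, 0.114) fell. All 9 of 9 myeloid genes rose (0.0874), with Fcer1g at 1.48 CPM in lymph node.

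Between blood and spleen, CD8 cells differed in few genes. The largest falls in blood were early response genes. Fos was 26.4 ± 1.12 CPM in blood and 223 ± 52.5 in spleen (SD, n = 4, log2 fold change -3.08, SE 0.16, adjusted p = 2.03e-08). Egr1 was 4.62 ± 2.61 and 40.3 ± 9.36 (-3.34, SE 0.25), Nr4a1 3.04 and 24.1 ± 9.40 (-3.02, SE 0.33). Zfp36, which destabilises cytokine messages, was 82.0 ± 3.53 and 324 ± 67.5 (-1.98), and Junb 478 ± 53.7 and 1177 ± 293 CPM (-1.30, SE 0.19, adjusted p = 0.00290). The other falls named were Dusp2, Dtx1, Sit1 and Tnfrsf9 (5.54 ± 2.33 against 15.3 CPM). P2ry10, a lipid receptor, was higher in blood (55.6 ± 9.08 against 23.8 ± 9.26 CPM, 1.19, SE 0.21, adjusted p = 0.00870). So were Tagap, a regulator of small GTPases (167 ± 18.3 against 85.5 ± 15.2 CPM), Fam46c, Rnf138, S100a10 (730.3 ± 186 against 445 ± 37.9 CPM) and the predicted gene Gm8369. Of the 18 immediate early and heat shock genes 8 fell, or 9 adjusted over the list alone (camera adjusted p = 4.03e-10, adjusted p = 0.268 with an estimated correlation). Circulating effector genes were higher by camera with none (0 of 9) passing, and 7 up and 1 down adjusted over the list alone (camera adjusted p = 0.00668, adjusted p = 0.268 with an estimated correlation). Cx3cr1 was 10.7 ± 6.81 against 4.18 CPM and Ly6c2 719 against 512 CPM, neither passing (Ly6c2 adjusted p = 0.0456 with the mouse as a block). Ribosomal proteins (0 of 16 passing, camera adjusted p = 0.00509) and effector Treg genes (1 down of 19, camera adjusted p = 0.045) were higher as lists, both with adjusted p = 0.65 with an estimated correlation. Myeloid genes had 2 of 9 up (adjusted p = 0.164). None of the genes named whatever the result passed without a block. Ccr7 was 764 against 439.5 CPM (adjusted p = 0.0574, 0.0192 with the mouse as a block), Gzmb 32.4 against 12.5 (0.319), Klrg1 17.4 against 3.21 (0.171) and Pdcd1 2.92 against 3.02 CPM (0.996).

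In numbers, 62 genes were higher and 124 lower in blood than in spleen (edgeR, 186 of 11396), and 143 and 202 with the mouse as a block. The count was 169 in mice 1 and 2 alone and 735 in mice 3 and 4 alone, 30 without mouse 1, 54 without mouse 2, 11 without mouse 3 and 63 without mouse 4. With library size scaling alone 30 genes were higher and 368 lower, with the median of all genes at -0.14 on the log2 scale.

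Between lymph node and spleen, CD8 cells of the lymph node had less of a set of effector genes. Tbx21 was 6.05 ± 0.816 CPM in lymph node and 17.3 ± 3.19 in spleen (SD, n = 4, log2 fold change -1.51, SE 0.15, adjusted p = 0.000287). S1pr5, a receptor for leaving tissues, was 0.0828 and 3.31 ± 1.56 (-5.13, SE 0.59), Cx3cr1 0.461 and 4.18 ± 0.925 (-3.24, SE 0.49), Zeb2 0.783 ± 0.909 and 3.31 ± 0.632 (-2.47, SE 0.43, adjusted p = 0.0203). With classes from clusters Zeb2 did not pass (0.0153, adjusted p = 1). The chemokine Ccl5 was 206 ± 48.7 and 762.3 ± 218 (-1.89, SE 0.36, adjusted p = 0.0405) and Fos 119 ± 17.9 and 223 ± 52.5 CPM (-0.90). Pim1, Ppp1r15a, Tagap and Ctla2a also fell. The interferon-induced GTPases Igtp (133 against 80.4 CPM, adjusted p = 0.00626), Tgtp2, Irgm1 and Gbp2, and Cxcr6 (116 ± 16.1 against 67.6 CPM), were higher. Circulating effector genes fell in 4 of 9, or 5 adjusted over the list alone (adjusted p = 0.000628 with an estimated correlation, as in the brackets that follow). Th1 genes fell in 2 of 12, or 6 with 1 up adjusted over the list alone (0.0239). The NK cell list (0 of 5, 1 down adjusted over the list alone, 0.0245) and myeloid list (0 of 9, 4 down adjusted over the list alone, 0.0344) were lower. Lost with an estimated correlation were cytotoxic (1 down of 17, adjusted p = 0.213), immediate early (1 down of 18, adjusted p = 0.213), interferon (2 up of 20, adjusted p = 0.721) and ribosomal lists (0 of 16, adjusted p = 0.652). In numbers, 11 genes were higher and 24 lower (edgeR, 35 of 11396), and 25 and 55 with the mouse as a block. The count was 189 in mice 1 and 2 alone and 3 in mice 3 and 4 alone. Without mouse 1 or mouse 2 the count was 2, and without mouse 3 it was 1. A split of these libraries by mouse pair gave more genes than the tissues did.

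**Figure D3:**
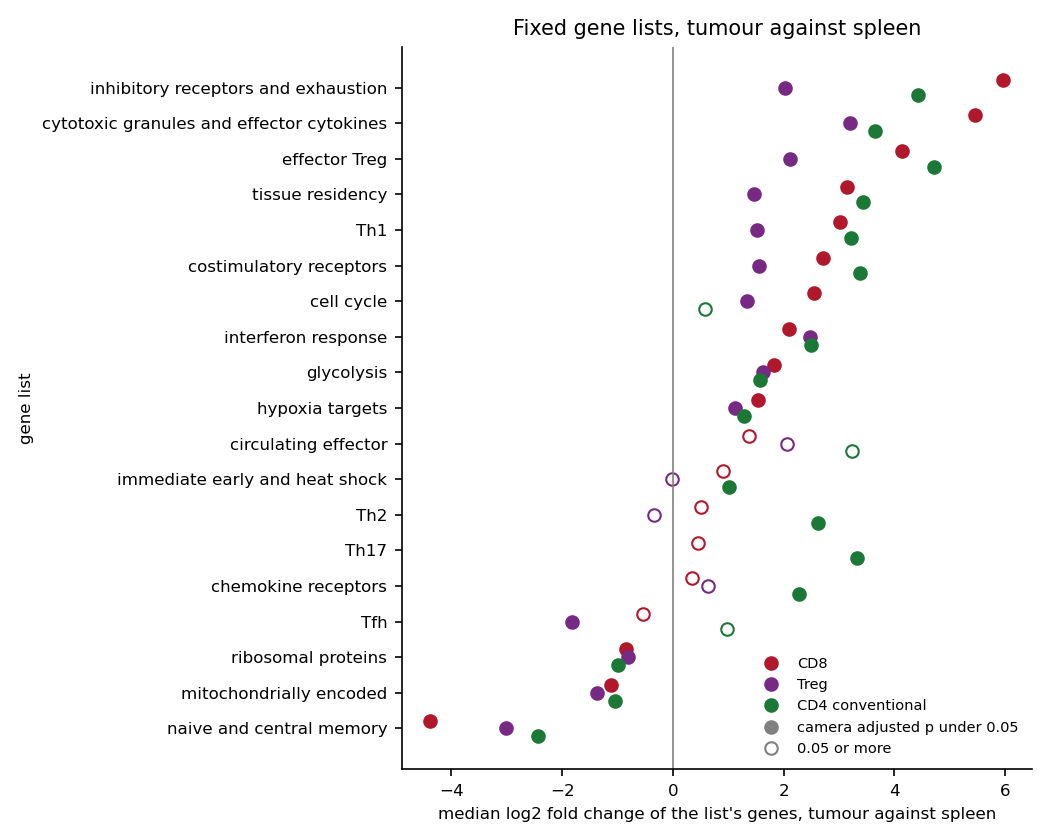
Median log2 fold change (linear axis) of the tested genes of each fixed list, tumour against spleen, in the 3 classes; filled symbols have camera adjusted p under 0.05 and open symbols do not. The exhaustion list had a median of 5.97 in CD8 cells.

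Treg of the tumour expressed more of the receptors and effector molecules of activated Treg than Treg elsewhere. Ccr8, a chemokine receptor, was 482 ± 83.1 CPM in tumour, 6.98 ± 2.42 in blood (SD, n = 4, log2 fold change 6.34, SE 0.47, adjusted p = 4.02e-09), 65.4 ± 26.3 in spleen (2.93, SE 0.32, adjusted p = 5.89e-07) and 67.5 ± 45.1 in lymph node (2.75, SE 0.31, adjusted p = 7.58e-07). Tnfrsf9, a costimulatory receptor, was 2342 ± 199 CPM against 30.4 ± 23.2, 229 ± 69.7 and 158 ± 50.7 (log2 fold change 6.10, 3.36 and 3.86). Il10, a suppressive cytokine, was 104 ± 8.24 CPM against no UMI in blood (at least 65.0-fold higher), 10.8 ± 6.58 in spleen and 10.6 ± 13.0 in lymph node (3.23 and 3.16). Klrg1, a marker of differentiated Treg, was 486 ± 80.2 CPM against 221 ± 98.2, 116 ± 55.2 and 22.4 ± 15.5 (1.27, 2.08 and 4.39, adjusted p = 0.00849, 0.00015 and 1.61e-07). Ccr8 lies on chromosome 9, 120092114 to 120094906 (ENSMUSG00000042262), Tnfrsf9 on chromosome 4, 150914562 to 150946102 (ENSMUSG00000028965), and Il10 on chromosome 1, 131019845 to 131024974 (ENSMUSG00000016529).

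Against spleen, 17 of 20 effector Treg genes rose and 1 fell (camera adjusted p = 1.3e-12, adjusted p = 0.00953 with an estimated correlation, given alone in later brackets). They included Tnfrsf4 (3010.3 ± 158 against 499.8 ± 206 CPM, log2 fold change 2.59, SE 0.26), Tnfrsf18 (1621 ± 129.8 against 364 ± 34.5 CPM), Icos (2090.0 ± 58.8 against 333 ± 57.5 CPM), the interleukin receptor Il2ra (846 ± 36.8 against 170.1 ± 54.5 CPM, 2.31) and Ctla4 (2441 ± 303 against 602 ± 172 CPM, 2.03, SE 0.21). Nrp1, a receptor of thymus-derived Treg, fell against spleen (23.8 ± 6.95 against 189 ± 23.2 CPM, -3.03, SE 0.20, adjusted p = 9.41e-10). Cytotoxic genes rose in 8 of 9 (8 up and 1 down adjusted over the list alone, 0.00481 with an estimated correlation). Gzmb was 3088 ± 713 against 69.5 ± 27.3 CPM (5.49, SE 0.55), Ccl4 557 ± 164 against 17.05 ± 34.1 (in spleen from mouse 3 alone, 0 without it, and adjusted p = 0.0631 with DESeq2), Ccl5 835 ± 50.3 against 86.0 and Nkg7 788 ± 299 against 61.5 CPM. Exhaustion genes rose in 10 of 11 with 1 down (0.00638). Lag3 was 803 ± 165 against 76.2, Entpd1 195 ± 21.6 against 16.3 and Havcr2 112 against 6.98 CPM. Glycolysis rose in 12 of 12 (0.00638), and hypoxia targets in 6 of 9 with 1 down, or 7 adjusted over the list alone (0.00638), with Bnip3 at 169.6 ± 21.03 against 8.90 CPM. Interferon genes rose in 18 of 20 (0.0413), with Ly6a at 4609 ± 343 against 533 ± 182 CPM. Naive genes fell in 9 of 12 (0.0138), with Tcf7 at 1.93 ± 0.394 against 117 ± 34.7 CPM (-5.87, SE 0.29, adjusted p = 3.9e-11). Mitochondrially encoded genes fell in 9 of 9 (0.00638).

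Calls lost with an estimated correlation in Treg against spleen were cell cycle (10 of 17 up, 14 adjusted over the list alone, adjusted p = 0.281, Mki67 139 ± 28.8 against 36.3 ± 9.31 CPM), costimulatory receptors (6 up, 2 down of 9, adjusted p = 0.099), Th1 (5 up, 1 down of 9, adjusted p = 0.0885), tissue residency (5 of 7 up, adjusted p = 0.0781), ribosomal proteins (16 of 16 down, adjusted p = 0.0781) and Tfh (2 up, 5 down of 7, adjusted p = 0.0514). The falling Tfh genes included Sh2d1a, a signalling adaptor of helper cells (60.9 ± 2.47 against 257 ± 29.7 CPM). Among the largest rises were the secreted factors Ccl3 and Metrnl and lactoferrin, Ltf, without a UMI in spleen (at least 47.0-fold, 44.8-fold and 36.5-fold higher). Others were Sv2c (311 ± 63.0 against 4.79 ± 4.54 CPM, 6.26), Ifitm3 and Il12rb2. The largest falls were those of Igfbp4 (0.573 against 214 ± 121 CPM, -8.16, SE 0.51), Tcf7, Dtx1, Nsg2, Atp1b1 and Evl. Not called were chemokine receptors (4 up, 2 down of 9, adjusted p = 0.0656), circulating effector (3 up, 1 down of 5, 0.856), immediate early (2 up, 5 down of 15, 0.812) and Th2 genes (0 of 3, 0.302). Of 6878 genes 1077 were higher and 1028 lower than in spleen, 1212 and 1118 than in blood, and 1266 and 1314 than in lymph node (edgeR). In mice 1 and 2 alone the totals were 2164, 2548 and 2667, and in mice 3 and 4 alone 1486, 1319 and 1884. The Treg sums held only 24 to 478 cells each.

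Against blood, tumour Treg had 222 ± 68.4 CPM of the chemokine Cxcl10 and 63.8 ± 29.3 CPM of the antiviral Mx1 where blood had no UMI (at least 144-fold and 43.7-fold higher). Lag3 rose from 3.83 CPM (log2 fold change 7.26) and Pdcd1 from 11.8 to 236 ± 52.1 CPM (3.70). Klf3 (5.98 against 284 ± 48.5 CPM, -5.60, SE 0.22, adjusted p = 1.25e-12) and Klf2 (122 against 1488 CPM) fell. Cytotoxic (9 of 9, adjusted p = 0.00283 with an estimated correlation, as in the brackets that follow), exhaustion (10 of 11, 0.00283), effector Treg (18 up, 2 down of 20, 0.0135), glycolysis (12 of 12, 0.0133) and hypoxia lists (6 up, 1 down of 9, 0.0443) rose. Naive (10 of 12, 0.0135) and mitochondrially encoded genes (8 of 9, 0.0133) fell. Called by camera but lost with an estimated correlation were interferon (18 of 20, adjusted p = 0.0915), immediate early (9 of 15, adjusted p = 0.15, Nr4a1 499 ± 30.7 against 12.9 CPM), cell cycle (13 of 17, adjusted p = 0.23, Tubb5 664 ± 148 against 315 ± 125 CPM, though lower in tumour with classes from clusters, at -0.91, adjusted p = 6.35e-05). So were costimulatory (6 up, 2 down of 9), Th1 (6 up, 2 down of 9) and ribosomal lists (15 of 16 down), each with adjusted p = 0.0915, and tissue residency (5 of 7, adjusted p = 0.15). Chemokine receptors (4 up, 3 down of 9), circulating effector (3 up, 1 down of 5), Tfh (3 up, 4 down of 7) and Th2 genes (2 down of 3) were not called.

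Against lymph node, Areg, which supports tissue repair, rose in tumour Treg from 5.42 ± 1.63 to 743 ± 158 CPM (n = 4, log2 fold change 7.16, SE 0.54, adjusted p = 4.14e-09). The chemokine receptor Ccr2 rose from 49.2 to 609 ± 65.7 CPM, and Frmd5 was at least 49.8-fold higher. Igfbp4, Dapl1, Nsg2, Tcf7, Id3 (4.04 against 217 ± 55.2 CPM) and Bcl2, a survival gene (8.11 against 279 ± 173 CPM), fell. Effector Treg (18 up, 1 down of 20, adjusted p = 0.0111 with an estimated correlation, as in the brackets that follow), cytotoxic (8 up, 1 down of 9, 0.00578), exhaustion (10 up, 1 down of 11, 0.0075), hypoxia (8 up, 1 down of 9, 0.0075), glycolysis (12 of 12, 0.0111), interferon (18 of 20, 0.0431) and Th1 lists (6 up, 1 down of 9, 0.0193) rose. Naive (10 of 12, 0.0165) and mitochondrially encoded genes (9 of 9, 0.0103) fell. Chemokine receptors (5 up, 2 down of 9, adjusted p = 0.0909), costimulatory receptors (6 up, 2 down of 9, adjusted p = 0.0909), tissue residency (4 of 7 up, adjusted p = 0.126) and ribosomal proteins (16 of 16 down, adjusted p = 0.0695) were lost with an estimated correlation. Cell cycle genes had 0 of 17 passing (edgeR, camera adjusted p = 0.957). Circulating effector, immediate early (6 up, 2 down of 15), Tfh (2 up, 3 down of 7) and Th2 genes were not called.

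**Figure D4:**
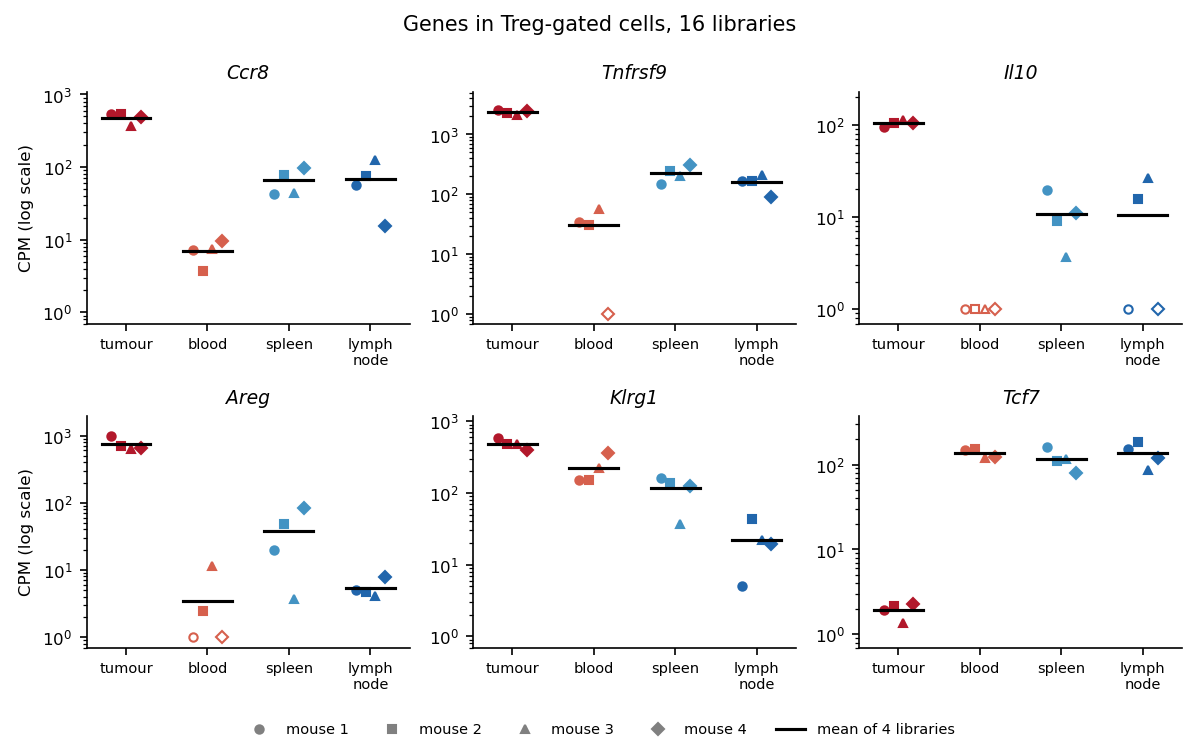
CPM after TMM scaling (log axis) of named genes in Treg by tissue; points are the 4 mice, lines the means, and open symbols at the bottom are libraries under 1 CPM, the lowest level drawn. Ccr8 averaged 482 CPM in tumour and 6.98 CPM in blood.

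CD4 conventional cells of the tumour had more transcripts of Ccl1, Csf2, Ifng and Bhlhe40 than those of the spleen. Ccl1, a ligand of the receptor encoded by Ccr8, was 485 ± 315 CPM in tumour and 0.400 ± 0.727 in spleen (SD, n = 4, log2 fold change 10.26, SE 1.02, adjusted p = 1.33e-06). Csf2, the growth factor GM-CSF, was 163 ± 73.8 and 0.661 ± 0.308 CPM (8.04, SE 0.41, adjusted p = 9.4e-11). Ifng was 221 ± 125 CPM in tumour against 15.5 ± 5.95 in spleen (3.79, SE 0.47, adjusted p = 3.93e-06), 2.74 ± 1.33 in blood (6.04) and 4.68 ± 4.94 in lymph node (6.11). Bhlhe40, a regulator of cytokine production, was 991 ± 319 against 23.2 ± 14.8, 6.66 and 11.01 CPM (5.39, 6.85 and 6.67). Cd40lg, the ligand by which helper cells license other cells, was 126 ± 39.8 CPM against 135 ± 12.3, 134 ± 41.5 and 133 ± 36.9 CPM and did not pass (adjusted p = 0.755, 0.896 and 0.783). In mice 1 and 2 alone it was higher than in blood (log2 fold change 0.61, adjusted p = 0.00289). On mm10, Ccl1 (ENSMUSG00000020702) lies on chromosome 11, 82176657 to 82305690, and Ifng (ENSMUSG00000055170) on chromosome 10, 118441046 to 118445892.

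Against spleen, all 20 effector Treg genes rose in these cells without Foxp3 UMIs (adjusted p = 0.0207 with an estimated correlation, as in the brackets after other lists). Among them were the receptors Icos (1137 ± 102 against 67.1 CPM), Tnfrsf4 (1246 ± 129 against 33.9 CPM) and Ccr8 (410.4 ± 92.3 against 3.36 ± 0.774 CPM, log2 fold change 6.94, SE 0.27) and Areg. The gate holds an unknown share of Treg, since only 84.5% of the tumour Treg cluster had a Foxp3 UMI. Here and below these rises can be partly theirs. Cytotoxic genes rose in 13 of 15 (0.0207). Gzmb was 576 ± 241 against 2.72 ± 0.519 CPM (7.74, SE 0.42) and Gzmc 337 ± 120.1 against 0.663 CPM. Exhaustion genes rose in 11 of 13 (0.0321), with Havcr2 at 54.3 ± 8.15 against 0.159 CPM. Glycolysis rose in 13 of 13 (0.0146), and hypoxia targets in 9 of 10 with Pdk1 down (0.0207). Costimulatory receptors rose in 7 with 1 down of 9 (0.0207) and tissue residency in 8 of 9, or 9 adjusted over the list alone (0.0207), with Cxcr6 at 745 ± 176 against 40.6 ± 14.6 CPM. Naive genes fell in 12 of 12 (0.00589). Igfbp4 was 4.40 ± 3.06 against 736 ± 129 CPM (-7.34, SE 0.32) and Tcf7 62.6 ± 10.7 against 400.1 ± 21.8 CPM (-2.67, SE 0.12). Mitochondrially encoded genes fell in 9 of 9 (0.0321). Il1r2 and Atf3 were also among the largest rises, and Pdlim4, Atp1b1, Dapl1, Treml2 and Als2cl among the largest falls.

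Other lists rose against spleen by camera and were lost with an estimated correlation: Th1 (12 of 12, adjusted p = 0.0528, with Il12rb2 at 109 ± 27.7 against 2.004 ± 0.918 CPM), interferon (20 of 20, adjusted p = 0.138, Ly6a 2623 ± 328 against 338 CPM), Th17 (4 of 4, adjusted p = 0.122, Rora 319 ± 27.1 against 24.4 ± 6.74 CPM), Th2 (4 of 5, adjusted p = 0.14, Gata3 108 ± 21.2 against 65.5 CPM). So were chemokine receptors (9 up, 2 down of 12, adjusted p = 0.19), immediate early (12 up, 2 down of 18, adjusted p = 0.406) and myeloid genes (5 of 5, adjusted p = 0.126, Cst3 189.6 ± 25.0 against 74.1 CPM and Fcer1g 8.72 against 0.655 CPM). The ribosomal list fell in 16 of 16 (adjusted p = 0.0979 with an estimated correlation). Within the immediate early list Nr4a1 rose (782 ± 264 against 54.0 CPM) and Jun fell (90.5 ± 36.8 against 477 ± 142 CPM, log2 fold change -2.40, SE 0.32, adjusted p = 9.71e-06). Cell cycle (2 up, 1 down of 17, adjusted p = 0.417), circulating effector (5 up, 2 down of 7, 0.098), Tfh (4 up, 2 down of 10, 0.0863), NK cell (2 of 4, 0.366) and NKT and MAIT lists (1 up, 1 down of 3, 0.897) were not called. Of 9909 genes 2486 were higher and 2342 lower than in spleen, 2508 and 2409 than in blood, and 2596 and 2530 than in lymph node (edgeR). The totals were 4564, 4664 and 5057 in mice 1 and 2 alone and 3911, 3769 and 3821 in mice 3 and 4 alone. With library size scaling alone, 2944 were higher and 1759 lower against spleen, and 3646 and 1406 against blood. Against blood the median of all genes moved by 0.23 on the log2 scale.

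Against blood, Penk, an opioid peptide precursor, rose from 0.425 to 670.5 ± 183 CPM (n = 4, log2 fold change 10.19, SE 1.01, adjusted p = 2.6e-07). Lag3 rose from 1.21 to 400.2 ± 97.5 CPM and Tnfrsf9 from 1.996 to 757 ± 50.7 CPM, and Ccl1 and Atf3 were at least 3050.2-fold and 427-fold higher. Th1 genes rose in 12 of 12 (adjusted p = 0.0489 with an estimated correlation, as in the next brackets). Naive (12 of 12 down, 0.00489), glycolysis (0.0198), cytotoxic (13 of 15, 0.0261), costimulatory (0.0261), exhaustion (12 of 13, 0.0261), tissue residency (9 of 9, 0.0261), effector Treg (20 of 20, 0.0292), hypoxia (7 up, 1 down, 0.0407) and mitochondrially encoded genes (8 of 9 down, 0.0334) were also kept with an estimated correlation. Interferon (20 of 20, adjusted p = 0.184), ribosomal (adjusted p = 0.0869), chemokine receptor (8 up, 2 down, adjusted p = 0.198), immediate early (13 up, 2 down, adjusted p = 0.198) and Th17 lists (3 of 4, adjusted p = 0.184) were lost. Cell cycle (7 up, 1 down of 17, camera adjusted p = 0.066) and Th2 genes (4 of 5, 0.0512) were called only with the mouse as a block (0.0459 and 0.0454). Tfh (5 up, 2 down of 10, 0.0512), circulating effector (0.119), NK cell (0.066), NKT and MAIT (0.458) and myeloid genes (2 of 5, 0.24) were not called.

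Against lymph node, Gzmb rose from 1.14 ± 1.22 CPM (log2 fold change 9.31, SE 0.48, adjusted p = 1.1e-10, n = 4), Ccr2 from 1.21 CPM (7.13), Tbx21 from 4.37 to 122 ± 37.4 CPM (5.25) and Klrg1 from 0.735 (mouse 3 alone) to 56.8 ± 13.9 CPM (6.90). The last 2 are among the circulating effector genes, which rose as a list (5 up, 2 down of 7, camera adjusted p = 0.0313, adjusted p = 0.155 with an estimated correlation). Kept with an estimated correlation were Th1 (12 of 12, adjusted p = 0.0347, and so in the next brackets), costimulatory (0.022), cytotoxic (14 up, 1 down of 15, 0.0199), effector Treg (20 of 20, 0.0236), glycolysis (0.0198), hypoxia (9 up, 1 down, 0.0199), and exhaustion (12 of 13, 0.0244). So were tissue residency (8 of 9, 0.0199), naive (0.00862) and mitochondrially encoded genes (8 of 9 down, 0.0351). Lost were Th2 (4 of 5, camera adjusted p = 0.0385, 0.0608 with the mouse as a block, adjusted p = 0.146 with an estimated correlation) and chemokine receptors (9 up, 2 down, adjusted p = 0.146). Also lost were interferon (20 of 20, adjusted p = 0.146), immediate early (12 up, 2 down, adjusted p = 0.256), Th17 (4 of 4, adjusted p = 0.122), ribosomal (adjusted p = 0.122) and myeloid genes (4 of 5, adjusted p = 0.13). Cell cycle, Tfh, NK cell, and NKT and MAIT lists were not called (adjusted p = 0.304, 0.121, 0.0825 and 0.143).

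T cell clones were large in tumour and small elsewhere. At 910 cells per library, 84.2%, 74.3% and 76.8% of tumour cells of mice 1, 2 and 4 belonged to clones of at least 2 cells. The shares were 1.98% in blood of mouse 4, 1.25% in spleen of mouse 3 and 0.319% and 1.73% in lymph node of mice 1 and 4. Over all cells the tumour shares were 89.8% (exact 95% interval 89.0% to 90.5%), 84.2% (83.2% to 85.2%) and 86.9% (85.9% to 87.8%). The largest tumour clones held 1457, 745 and 1969 cells (23.9%, 14.7% and 39.2% of the library), and the largest blood clone 9. Within tumour, at 188 cells per gate, CD8 cells were in such clones in 83.6% ± 3.197, CD4 conventional cells in 44.1% ± 13.7 and Treg in 47.0% ± 2.36 (SD, n = 3). CD8 exceeded both in 3 of 3 mice (exact permutation p = 0.10, the smallest that 3 against 3 allow), and CD4 conventional and Treg did not differ beyond their spread (exact permutation p = 0.70). Tissues other than tumour had 1 or 2 TCR libraries each, so their difference from tumour was not tested.

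Clones of the tumour were also found in blood and lymph node of the same mouse. In mouse 4, tumour and blood shared 17 clones, which held 2030 of 5019 tumour cells (40.4%, exact 95% interval 39.1% to 41.8%) and 27 of 910 blood cells (2.97%, 1.96% to 4.29%). Its tumour and lymph node shared 33 clones, which held 2554 tumour cells (50.9%) and 39 of 1427 lymph node cells (2.73%, 1.95% to 3.72%). The clone of 1969 cells was among both. Of the shared tumour cells 1966 and 2436 were in the CD8 gate. Of the 39 lymph node cells 13 were CD8 and 14 CD4 conventional. Blood and lymph node of mouse 4 shared 7 clones, and tumour and lymph node of mouse 1 shared 8, with 37 and 11 cells. At 910 cells per library, means of 6.81, 11.7, 4.47 and 0.595 clones were shared in that order. The 50.9% was then 31.9% (SD 19.4 over draws). As a background, 1 of 17 pairs of libraries of different mice shared nucleotide clones (2).

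**Figure D5:**
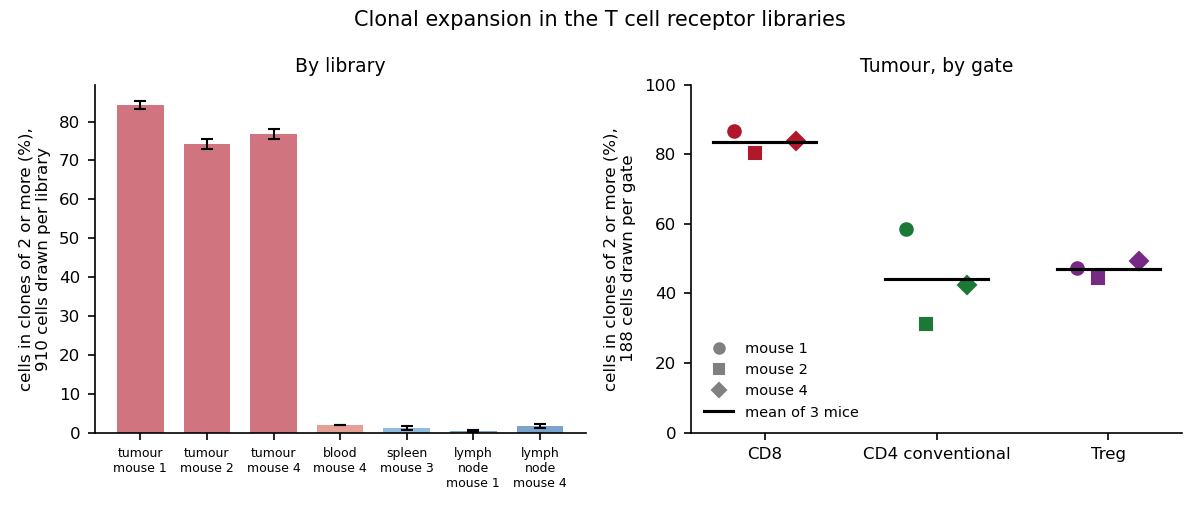
Percent of cells in clones of at least 2 cells (linear axes from 0). Left, each TCR library at 910 cells, with whiskers of 1 SD over random draws; right, tumour cells of each gate at 188 cells, points the 3 mice and lines their means. The tumour libraries lie between 74.3% and 84.2%.

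Tumour CD8 cells of expanded clones (at least 3 cells) had more granzyme and inhibitory receptor transcripts. Those seen as the 1 cell of their clone had more of naive genes. Gzmd was 187 ± 161 CPM in expanded and 26.2 ± 22.7 in single clones (SD, n = 3, log2 fold change 2.85, SE 0.14, adjusted p = 1.96e-07), and Gzmf 692 ± 549 and 173 ± 182 (2.20, SE 0.19). Prf1, the pore former perforin, was 361 ± 192 and 124 ± 69.6 (1.56, SE 0.09), Havcr2 162 ± 26.1 and 56.5 ± 11.8 (1.51, SE 0.09), and Pdcd1 1128 ± 80.7 and 503 ± 63.0 CPM (1.17, SE 0.08, adjusted p = 4.38e-06). Klra7, a natural killer receptor of the Ly49 family (chromosome 6, 130218605 to 130233322), was 0.434 ± 0.0372 against 52.9 ± 4.91 CPM (-6.91, SE 0.19, adjusted p = 5.49e-09). Tcf7 was 2.83 ± 1.49 against 93.9 ± 27.3 (-5.03, SE 0.31). S1pr1, which guides cells out of tissues, was 3.43 ± 2.24 against 82.3 ± 41.6 (-4.63) and Klrg1 6.20 ± 1.55 against 26.1 ± 4.12 CPM (-2.09). Gm156, Gzme, Gzmc and Igfbp7 were the other largest rises, Nsg2 and Klf3 among the largest falls. Lag3, Nr4a2, Tigit, Tox, Ifng, Cxcr6, Gzmb (2006 ± 207 against 1255 ± 299 CPM, 0.70, SE 0.09), Mki67 (117 ± 11.3 against 77.7 ± 27.1 CPM, 0.59) and Ctla4 (617 against 472 CPM, 0.36, adjusted p = 0.00982) were higher and Ccr7 was lower in expanded clones. Each gene that passed moved the same way in 3 of 3 mice. Without the mouse block Gzmd (adjusted p = 0.281), Gzmf (0.393), Gzme (0.283), Gzmc (0.355), Prf1 (0.176), Gzmb (0.0763), Gm156 (0.0545), Igfbp7 (0.186), Mki67 (0.222) and Ctla4 (0.2701) no longer passed.

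By list 11 camera calls were made, each lost with an estimated correlation (adjusted p = 0.522). In these 13 of 14 exhaustion genes were higher in expanded clones (1 more fell adjusted over the list alone), 14 of 17 cytotoxic, 15 of 17 cell cycle (17 adjusted over the list alone), 11 of 13 glycolysis and 6 of 11 hypoxia with 1 down. Of 12 Th1 genes 8 rose and 2 fell, among them the chemokine receptor Cxcr3 (38.4 ± 11.1 against 115 ± 7.62 CPM). Naive genes fell in 11 of 12, ribosomal proteins in 14 of 16, mitochondrially encoded genes in 9 of 9 and Th17 genes in 2 of 3. Interferon response genes fell in 12 of 20 with 1 up, with Oasl2 at 7.73 against 54.5 CPM (log2 fold change -2.78). Without the mouse block the hypoxia call was lost (adjusted p = 0.0965). Not called with the block were chemokine receptors (2 up, 6 down of 10, adjusted p = 0.101), Tfh (1 up, 5 down of 9, 0.0583), both called without it (0.0131 and 0.0179). Also not called were circulating effector (3 up, 4 down of 8), costimulatory (2 up, 2 down of 9), effector Treg (6 up, 8 down of 20), immediate early (4 up, 6 down of 18), Th2 (2 down of 3), tissue residency (4 up, 5 down of 10), myeloid (1 up, 1 down of 9), NK cell (2 up, 3 down of 5) and NKT and MAIT genes (1 down of 3). Of 11150 genes 1169 were higher and 1204 lower in expanded clones (edgeR with the mouse as a block). The total was 640 without the block and 1218 without mouse 1. Expanded groups held 4966, 3560 and 3367 cells and single groups 247, 311 and 252. The means were 10745, 12288 and 9668 UMIs per cell against 9435, 9924 and 7782.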

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

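The counts of other splits and the tests of technical explanations in this part were chosen only after the results were seen, apart from 3 of the 6 tests for Spp1, which had been fixed before.

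Cells with UMIs of both Cd4 and Cd8a or Cd8b1, which lie outside the gates, were more frequent in lymph node and spleen of mice 3 and 4 (14.02% and 16.4%, 9.13% and 13.3%) than of mice 1 and 2 (5.88% and 6.73%, 4.78% and 6.30%). In tumour they were also more frequent in mice 3 and 4 (7.65% and 5.46% against 3.24% and 4.64%), and in blood less (3.499% and 2.75% against 4.37% and 4.02%). The tables argue against 2 cells in 1 droplet, since in these 4 libraries the median UMIs of such cells were at most 0.975 times those of cells in 1 gate. Free RNA of CD8 cells in the droplets of Cd4 cells cannot be told apart from expression: Cd8b1 per Cd8a UMI in CD4 clusters was 2.36 and 2.41 times that in barcodes of at most 100 UMIs in spleen and 2.00007 and 1.89 times in lymph node of mice 3 and 4. The bound against free RNA, over 2 in each library, was thus passed in 3 of 4 libraries, in 1 of them barely. The mouse pairs are no group of the design, so no biological explanation was tested.

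Spp1 was among the largest rises in tumour CD8 cells (383, 302, 96.9 and 41.7 CPM in mice 1 to 4), and macrophages express it too. The tables argue against free RNA as the whole source, since the lower of Treg and CD4 conventional cells had at most 0.399 times the Spp1 UMIs per CD8 cell (upper 95% limit). They also argue against droplets shared with myeloid cells like the myeloid cluster. UMIs of Lyz2, Apoe, C1qa, C1qb and C1qc per Spp1 UMI were at most 0.0155 times those in it. This cannot judge myeloid cells richer in Spp1. CD8 cells without a UMI of the myeloid list other than Cst3 had at least 0.838 times the Spp1 of all CD8 cells. A test fixed before points the other way. CD8 cells without a UMI of the whole list had 0.315 to 0.462 times the Spp1, under the bound of 0.5 set for droplets shared with myeloid cells in each of 4 libraries. It was set aside only after its values were seen, because the list held Cst3, seen in 75.6% of tumour and 37.6% of spleen CD8 cells, so that the test selected on the cells' own expression and on depth. Free RNA as part of the source cannot be told apart from expression: Spp1 UMIs per Treg were 0.0532, 0.329, 0.145 and 0.307 times those per CD8 cell in mice 1 to 4 (the bound against it, under 0.2 in each library, was met in mice 1 and 3 only), and the level in CD8 cells as a share of free RNA was at least 2.48 times that of 5 myeloid genes (between 2 and 5). The sort selects against carcinoma cells, and too few members of their list could be tested. Droplets shared with them were not tested, so transcription by CD8 cells was not shown.

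In CD8 cells of the tumour of mouse 3, Tcf7 (22.7 CPM, 5.89 to 8.20 in the other mice) lay far above the other libraries. Such a far sample was seen in 1 of 108 groups of the genes reported, and chance gives about 1 in 20, or 5.4.

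Of 6 tests of a difference between classes in the genes reported, 2 passed (edgeR interaction). For Klrg1 against blood, CD8 cells and Treg differed by -2.28 in log2 fold change (adjusted p = 0.000153). With classes from clusters, which hold no blood Treg of mice 3 and 4, the CD8 value was 2.999 and the Treg value stayed higher, and their difference was not tested. For Ifng against spleen, CD8 and CD4 conventional cells differed by 1.76 (adjusted p = 1.21e-05).

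In the 7 TCR libraries 21027 barcodes with a productive chain lay outside the table, 2181 of them with 1 TRA and 1 TRB contig. In the 16 matrix files 64064 of 126279 barcodes of at least 1500 UMIs lay outside it.

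Chance could be excluded for each tumour comparison, since only 1 of 35 splits of the 8 libraries, the real one, gave as many genes. In CD8 cells the real and highest other counts were 7161 and 311 against blood, 7425 and 0 against spleen, and 7484 and 1 against lymph node. In Treg they were 2330 and 15, 2105 and 8, and 2580 and 7, and in CD4 conventional cells 4917 and 25, 4828 and 0, and 5126 and 11. Among the 8 splits that, like the real one, part the 4 pairs of libraries of a mouse, the highest other count was 4 for CD8 tumour against blood and 0 in the other tumour comparisons. These 8 are too few for a share under 0.05. For CD8 blood against spleen the real split gave 186 genes and the next, mice 1 and 2 against mice 3 and 4, gave 174 (1 of 35 splits as large). For CD8 lymph node against spleen chance could not be excluded even over all splits, as 2 of 35 gave at least the real 35 genes. The larger, at 620, parts mice 1 and 2 from mice 3 and 4 and points to a structure of the samples. With the mouse as a block the tissue gave 80 genes, and among the 8 splits that part the pairs of a mouse the highest other count was 0, as for blood against spleen. The 10 splits of the clone comparison are too few for a share under 0.05 (1 as large, real 2373, highest other 0).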

How the results depend on the processing

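Alternatives without the tenth of cells with the highest doublet scores and with library size scaling alone were chosen only after the results were seen. Among counts of genes 151 alternative values stayed within 1.5 times the reported count and 23 did not, among counts of lists 57 and 9, and among clone values 33 did not move and 9 did. Of share differences 141 kept direction and side of the threshold, 1 newly passed it and 1 no longer did. Of values of named genes 11198 kept both, 161 were no longer past the threshold, 60 newly passed it and 4 changed sign. The cause was not tested, except where the setting itself states it.

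Over the settings fixed beforehand the counts for tumour against blood, spleen and lymph node ran over 5255 to 7822, 6041 to 8336 and 5929 to 8362 in CD8 cells, 1319 to 3737, 1453 to 3110 and 1805 to 4066 in Treg, and 3769 to 5716, 3783 to 5662 and 3821 to 5828 in CD4 conventional cells. The Treg ends beyond 1.5 times were classes from clusters (3737 against blood, 4066 against lymph node), which hold no Treg of mice 3 and 4 in blood and spleen, and mice 3 and 4 alone against blood (1319). The comparisons without tumour moved most. CD8 blood against spleen (186) gave 345 with the mouse block, 410 with DESeq2 (203 higher, 207 lower), 398 with library size scaling alone, 73 from these 2 tissues alone, 735 in mice 3 and 4 alone and 11 to 63 with 1 mouse left out. CD8 lymph node against spleen (35) gave 80 with the block, 110 with DESeq2, 21 with library size scaling alone, 16 from these 2 tissues alone, 189 in mice 1 and 2 alone, 3 in mice 3 and 4 alone and 1 to 25 with 1 mouse left out. The clone comparison (2373) gave 640 without the mouse block and 1218 to 2458 with 1 mouse left out.

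With an estimated correlation the number of lists called fell to 0 of 15, 2 of 14 and 2 of 16 in CD8 cells (tumour against blood, spleen and lymph node), 0 of 4 for blood against spleen, 4 of 8 for lymph node against spleen, 7 of 14 and 8 of 14 in Treg (blood, spleen), and 9 of 17 and 10 of 18 in CD4 conventional cells (spleen, lymph node). It stayed within 1.5 times at 9 of 13 in Treg against lymph node and 10 of 15 in CD4 conventional cells against blood. The mouse block changed no other call of a list or share than those given beside them. With it 8 values of named genes newly passed, among them Klra9 (adjusted p = 0.0286) in CD8 blood against spleen, and Ifng (0.0361), Junb (0.00615), Klrk1 (0.0258) and Nr4a1 (0.0497) in CD8 lymph node against spleen, each lower in lymph node. In the clone comparison 27 no longer passed without it.

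In cycling Treg, tumour minus blood was 3.41 percentage points at 1000 UMIs and no longer passed (adjusted p = 0.429). Tumour minus spleen was 9.71 without thinning and passed (adjusted p = 0.0312). At 2000 UMIs it was -0.332 in mice 3 and 4 alone, where spleen had 0 of 31 and 1 of 10 cycling Treg. At 1000 UMIs the difference from lymph node could not be computed. With all cells, the shares in clones were 89.8%, 84.2% and 86.9% in tumour of mice 1, 2 and 4, 4.15% in spleen of mouse 3 and 1.76% in lymph node of mouse 1, and tissues shared 8, 17, 33 and 7 clones, since more cells show more clones.

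Named genes that changed sign were Klrg1 in CD8 cells, tumour against blood, at 2.999 with classes from clusters (adjusted p = 0.000155, reported -0.87), Zeb2 in CD8 cells, lymph node against spleen, at 0.0153 (adjusted p = 1, reported -2.47), Tubb5 in Treg, tumour against blood, at -0.91 (adjusted p = 6.35e-05, reported 1.02), both also with classes from clusters, and Cd40lg in CD4 conventional cells, tumour against blood, at 0.61 in mice 1 and 2 alone (adjusted p = 0.00289, reported -0.05). Treg numbered 24 to 478 cells in a library.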

Other observations

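The tests of the shared receptor pairs were chosen only after the result was seen. Tumours of different mice held T cells with the same CDR3 amino acid pair. Of 14175 amino acid pairs of TRA and TRB CDR3 sequences in the 7 libraries, 19 were found in at least 2 mice, and all 19 were in tumours of at least 2 mice. They held 499 cells, 337 of them CD8, and 18 of them had at least 2 cells in a tumour. The pair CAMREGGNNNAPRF and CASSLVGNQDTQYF was seen in 161 cells (155 CD8) of 4 mice with 13 nucleotide pairs and more than 1 V gene of each chain, so whole receptors were not shown to be the same. The pair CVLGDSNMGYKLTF and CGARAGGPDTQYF was seen in 78 cells of 2 mice, 66 of them CD4 conventional. Within 1 tumour, 24 of 2833 amino acid pairs were written by at least 2 nucleotide pairs. Carry-over between libraries would copy the nucleotides, and only 2 of the 19 pairs (10.5%) had the same nucleotide pair in 2 mice. These are the pair of 161 cells and a pair of 62 cells, and for the nucleotide pairs they share carry-over stays open. Relative to the number of clone pairs compared, tumours of different mice shared 47.5 times as many pairs as other libraries of different mice (21 over 3 pairs of libraries against 11 over 14), which argues against overlap by library size alone. A candidate explanation is selection of alike CDR3 sequences by antigens of the same tumour line, which was not tested against other antigens, since each mouse carried the same line.

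The largest clones did not match across mice. Mouse 1 had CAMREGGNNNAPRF with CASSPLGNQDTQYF in 1457 cells, mouse 2 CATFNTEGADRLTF with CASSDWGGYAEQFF in 745 and mouse 4 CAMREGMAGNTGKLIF with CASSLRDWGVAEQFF in 1969. The TRA sequence of the first is also that of the pair seen in 4 mice, and its TRB nucleotide sequence was seen in 0 cells of the other mice, as was that of mouse 2. The TRB of mouse 4 was seen in 4 cells of other mice, 0 with the same TRA. The invariant TRAV11 to TRAJ18 chain, the mark of invariant natural killer T cells, was carried by 93 of 3471 spleen cells of mouse 3 (2.68%, exact 95% interval 2.17% to 3.27%), 28, 38 and 4 tumour cells of mice 1, 2 and 4 (0.459%, 0.750% and 0.0797%), 5 blood cells of mouse 4 (0.549%) and 6 and 5 lymph node cells of mice 1 and 4 (0.104% and 0.3504%). The TRAV1 to TRAJ33 chain of mucosal-associated invariant T cells was in 0 to 10 cells per library. A cluster of 224 cells of mice 1 and 2, 89.3% from spleen, was led by Zbtb16, Klrb1c and Il4, genes of natural killer T cells. It thus held none of the 93.

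Clusters of naive and blood cells from mice 3 and 4 were led by ribosomal pseudogenes (Gm10260, Rpl10-ps3 and Rpl36-ps3), and the matching clusters from mice 1 and 2 by other genes, the cause of which was not tested. The table held only cells with exactly 1 productive TRA and 1 productive TRB contig wherever this was tested, so cells with 2 TRA chains, or with a chain missed, are outside each value given here.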
